A study of Mus musculus with 11 samples.

How the data were processed

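RNA was extracted from mouse bone marrow-derived macrophages, 7 control libraries and 4 libraries of cells treated with 0.5 µg/ml CYR61 for 24 h. Per the labels' protocols, libraries were made from total RNA after ribosomal RNA was removed, with random priming, and sequenced as paired reads on an Illumina instrument. Ribosomal RNA removal keeps unspliced and non-polyadenylated transcripts, so counts of a gene can include RNA that was not yet spliced where the authors' counting included it. The labels do not say whether the libraries keep the strand, so reads of a gene and of an antisense gene that overlaps it cannot be told apart here. The sources used here do not say whether control cells received a vehicle, or whether the libraries came from separate animals or cultures.

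Per the submitters' processing notes, DRAGEN was used upstream, and its version, its role, the genome build and the annotation are not given in the sources used here. The authors deposited a table of expected counts (estimated counts) per Ensembl gene that are not normalized, with 1 column per library. Per the file's values, 88.6 to 89.4% of the estimated counts in a library were whole numbers, tested as exact equality to the rounded value. This is over all 55487 gene IDs and takes zeros as whole. Only 21014 to 21801 genes per library had a rounded count above 0, so the share among genes with counts is lower. Counts that are not whole arise where reads are shared between features, so values of genes with near-identical copies (such as the Gbp, Ifi, Ifit, Oas, Slfn, Fcgr and Ly6 families) are uncertain. The table has 55774 rows and 55487 gene IDs, since 168 IDs stand on several rows with identical values, and the 287 extra rows were dropped. The authors also deposited a table of their comparison with log2 fold changes, intervals, p-values, adjusted p-values, scores (moderated t, log odds and a signed linear fold change) and log2 CPM per library. The method behind it is not given in the sources used here; several of its column names (such as AveExpr, t and B) are those of limma, and others are not. Each library's deposited log2 CPM equalled the log2 of the CPM of the count plus 0.5, shifted by 1 constant per library (-0.015 to 0.0594), to within 5.5e-09. The deposited p-values and t scores of the authors fit 25.8 degrees of freedom (median of 134 genes), and a limma-voom fit with library quality weights on the 11 libraries had 16.8. The authors' fit was therefore not rebuilt exactly. The reason was not tested, and use of further libraries is only among the possibilities. The authors' log2 fold changes differed from that fit by a median of 0.0016, and from limma-voom without weights by 0.016. No per-sample column without a sample was found.

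Groups were taken from the labels. Estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16: filterByExpr with default settings left 15135 genes, TMM factors scaled the libraries, and glmQLFit and glmQLFTest compared CYR61 with control over all 11 libraries without covariates. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The biological coefficient of variation was 5.64%. CPM values are TMM-scaled. Gene lists (18) and marker lists of 11 cell types were written before the data were examined. Each was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg within the gene lists and within the marker lists, and again with an estimated correlation. Library measures were compared by exact permutation of the group labels over all 330 splits.

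Genes named in the text follow a rule set before the data were examined. It takes Ccn1, Itgam, Itgb2, Itgav and Itgb3; the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 CPM and a named symbol; up to 4 members of lowest p with a mean of at least 1 CPM from each gene list; the 5 called genes of lowest p in each direction; and up to 3 members of lowest p from each marker list that passed. Other genes are said to have been chosen after their values were seen.

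The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, no TMM, no filter, a mean of at least 1 CPM, protein-coding genes only, no mitochondrial or ribosomal RNA genes, the replicate number as a block, 1 surrogate variable (sva 3.50.0), leaving out each library, a 1.5-fold minimum, an adjusted p under 0.01, and for lists an estimated correlation and fry. Chosen after seeing the data were a correction of GC content and length trends per library, limma-voom with library quality weights, a fit without CYR61 replicates 1 and 4 and the 8 libraries of the block without the block. GC content and length came from GENCODE M21 transcripts matched by Ensembl gene ID for 99.8% of tested genes; this annotation may differ from the one the authors used and served no other purpose. On simulated counts for the comparison of CYR61 with control, with 200 genes changed and 14925 genes tested, the edgeR step recovered 27 of 67 genes changed 1.2-fold (40.3%), 48 of 67 changed 1.5-fold (71.6%) and 52 of 66 changed 2-fold (78.8%), and 8 of its 135 calls were unchanged genes. With 1 of 18 lists raised 1.2-fold in a simulation, camera called that list and 0 others. The simulated genes were drawn independently, whereas the estimated correlation in the data was 0.501 for the interferon list and 0.839 for the mitochondrial list. The simulation therefore cannot show false calls that arise from correlated members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.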

Results

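Gene expression was measured by RNA sequencing in cultured mouse macrophages that were or were not exposed to the protein CYR61. The cells were bone marrow-derived macrophages, which are grown from marrow cells of C57BL/6J mice in a medium that drives them to become macrophages. CYR61, also called CCN1, is a secreted matrix-associated protein that binds integrins and heparan sulfate proteoglycans on the cell surface. Of the 11 libraries, 7 came from control macrophages and 4 from macrophages treated with 0.5 µg/ml CYR61 for 24 h. The control libraries held 14912123 to 21047654 counts and the CYR61 libraries 17390272 to 20760322. The number of counts did not separate the groups (two-sided exact permutation test over 330 splits, p = 0.791, adjusted over 6 library measures p = 0.9). The shares of counts in mitochondrially encoded genes (1.38 ± 0.106% against 1.25 ± 0.203%; exact permutation p = 0.206, adjusted p = 0.723) and in ribosomal RNA (0.439 ± 0.197% against 0.883 ± 1.02%; exact permutation p = 0.3, adjusted p = 0.723) did not pass either. The smallest p this exact test can give is 0.00303. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per gene of 2.90 to 10.6 between controls. It was 3.48 to 9.07 between CYR61 replicates 1 to 3, and 19.2 to 33.4 in pairs with CYR61 replicate 4. The measure includes ribosomal RNA genes, which held 2.41% of counts in CYR61 replicate 4 and 0.246 to 0.562% in the other CYR61 libraries. How much of the high values they account for was not tested. The labels do not say whether libraries came from separate mice or cultures, so the p-values measure the spread between these libraries, which may be technical. Values below are CPM, counts scaled to a common library total with TMM factors, as mean ± SD with n = 7 control and n = 4 CYR61 libraries, and folds are those of the edgeR fit. The genome build and annotation are not given in the sources used here, so genes are given by symbol and no coordinates are printed.

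The design has 1 comparison, which asks how exposure to CYR61 changed the macrophage transcriptome. Among the genes that rose most in CYR61-treated macrophages were Saa3, Cfb and C3, which act in the acute phase response and in complement. Saa3, an acute phase serum amyloid A protein made by macrophages, rose 26.9-fold, from 1.66 ± 0.286 to 45.0 ± 16.6 CPM. The complement genes Cfb (factor B) and C3 rose 9.35-fold (1.34 ± 0.419 to 12.4 ± 4.98 CPM) and 3.14-fold (45.6 ± 4.05 to 143 ± 24.7 CPM). Most changes were much smaller: the median fold of the genes that rose was 1.18, and the median fall of the genes that fell was 14.1%. Interferon-stimulated genes and genes of cholesterol biosynthesis rose as groups. In the cell cycle list 12 of 32 genes fell, all of which act in G2 or mitosis, but the list did not pass when the correlation between its genes was estimated (camera, Benjamini-Hochberg adjusted p = 0.22 with an estimated correlation).

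By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 1204 of 15135 genes tested passed the threshold of 0.05, of which 806 were higher and 398 lower with CYR61. Changes of at least 1.5-fold were found for 121 of the higher and 31 of the lower genes, and of at least 2-fold for 54 and 8. Over all 15135 genes tested, all 4 CYR61 libraries lay above or all below the 7 controls in 1083 (7.16%), against 0.606% for a gene without a difference, and 870 of these were among the 1204. The first principal component held 17.6% of the variance and placed every CYR61 library (11.1 to 21.7) above every control library (-19.8 to 0.04). The controls themselves differed along it, from -19.8 in replicate 1 to 0.04 in replicate 7, with replicates 2 to 6 at -14.3 to -6.11. The deposited sample numbers put all controls before the CYR61 libraries. If they follow the order of processing, an effect of that order cannot be told apart from CYR61, which was not tested. The split between higher and lower genes depended on the scaling: 66.9% of called genes were higher with TMM, and 36.1% (529 higher, 938 lower) when counts were scaled by library size alone, which moved the median log2 fold change of all tested genes from -0.008 to -0.052. Without CYR61 replicate 2 the count fell to 788 genes (583 higher, 205 lower).

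**Figure D1:**
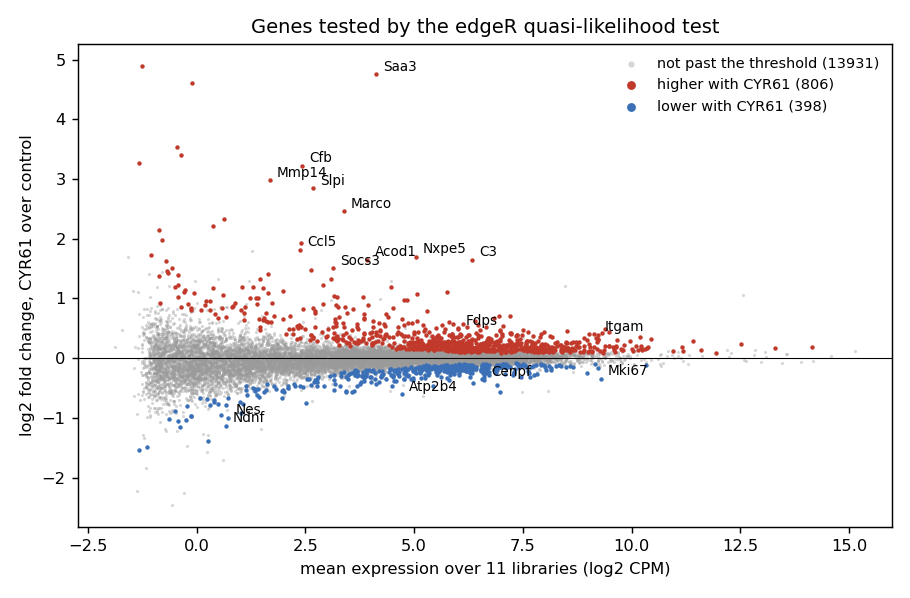
Log2 fold change of CYR61 over control (vertical axis) against mean expression over the 11 libraries in log2 CPM (horizontal axis), with 1 point for each of the 15135 genes tested by edgeR. The 806 genes higher with CYR61 are red, the 398 lower genes blue and the others grey; Saa3 stands at 4.75 and Ndnf at -1.13, and most coloured points lie close to 0.

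The 10 largest rises among named genes with a mean of at least 1 CPM were those of Saa3, Cfb, Mmp14, Slpi, Marco, Pilra, Hp, Ccl5, Nxpe5 and C3. Mmp14, a membrane-bound matrix metalloproteinase, rose 7.88-fold (0.921 ± 0.289 to 7.18 ± 2.16 CPM), and Slpi, a secreted inhibitor of leukocyte proteases, rose 7.18-fold (1.96 ± 0.319 to 14.1 ± 4.03 CPM). The scavenger receptor gene Marco rose 5.49-fold (3.93 ± 1.04 to 21.8 ± 6.34 CPM) and the receptor gene Pilra 5.01-fold (0.62 ± 0.255 to 3.18 ± 1.19 CPM). Haptoglobin (Hp) rose 3.82-fold, the chemokine gene Ccl5 3.52-fold (2.70 ± 0.537 to 9.54 ± 1.63 CPM) and Nxpe5 3.25-fold (18 ± 1.96 to 58.7 ± 11.2 CPM). The lowest p-values among the rises were those of Saa3, C3, Slpi, Nxpe5 and the endothelin receptor gene Ednrb, which rose 2.15-fold (38.4 ± 3.02 to 82.4 ± 10.5 CPM). The adjusted p of these 5 genes ran from 6.7e-10 to 2.08e-08 (edgeR, Benjamini-Hochberg), and for each of them all 4 CYR61 libraries stood above all 7 controls.

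The 10 largest falls were in genes of low expression. Ndnf fell from 1.98 ± 0.584 to 0.902 ± 0.275 CPM (0.457 times control), Nes, which encodes the intermediate filament nestin, from 2.02 ± 0.419 to 1.01 ± 0.301 CPM, and Dcst1 from 1.795 ± 0.377 to 0.925 ± 0.195 CPM. Tox2, Abca6, Omp, Lrrc18, Sox4, Cmah and Dkk2 stood at 0.53 to 0.65 times control, with control means of 1.53 to 4.48 CPM. Among these 10, Omp and Lrrc18 were closest to the threshold, with adjusted p = 0.0484 and 0.0458 (edgeR, Benjamini-Hochberg). Of 25 alternatives, 16 lost the call of Omp, DESeq2 and limma-voom among them, 10 that of Lrrc18, 7 that of Abca6, 6 that of Cmah and 5 that of Dkk2. The falls of lowest p were in more strongly expressed genes. The plasma membrane calcium pump gene Atp2b4 fell from 30.0 ± 0.885 to 19.7 ± 1.44 CPM, the inhibitory receptor gene Cd300a from 166 ± 3.004 to 137 ± 2.99 CPM, and the mitotic genes Cenpf, Mki67 and Aspm to 0.78, 0.787 and 0.802 times control. Their adjusted p ran from 5.02e-07 to 1.58e-05 (edgeR, Benjamini-Hochberg).

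**Figure D2:**
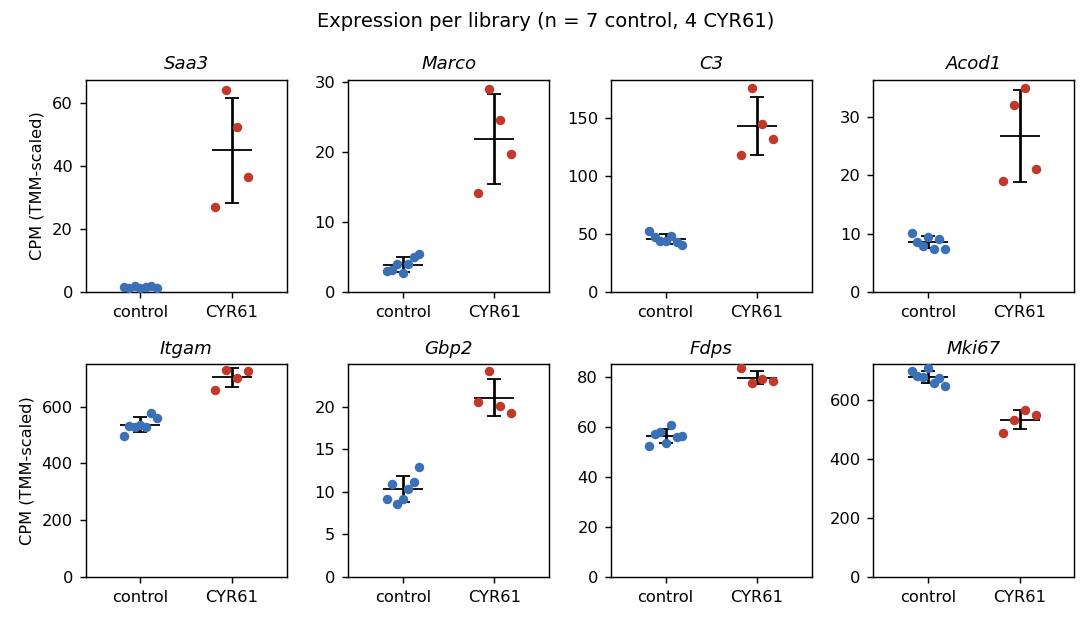
TMM-scaled CPM of 8 genes in each of the 7 control (blue) and 4 CYR61 (red) libraries, with the vertical axis starting at 0 in each panel, the horizontal bar at the mean and the error bar spanning 1 SD on each side. In all 8 panels the 4 CYR61 points lie clear of the 7 control points: above them for Saa3, Marco, C3, Acod1, Itgam, Gbp2 and Fdps, and below them for Mki67.

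CYR61 is known to bind the integrins alpha-M beta-2 and alpha-V beta-3, so their genes were examined whatever their result. Itgam rose 1.31-fold, from 537 ± 26.1 to 703 ± 33.1 CPM, and its partner Itgb2 rose 1.15-fold, from 764 ± 7.84 to 875 ± 13.3 CPM. Itgb3 fell from 10.8 ± 0.838 to 7.88 ± 0.798 CPM (0.725 times control). Itgav was measured at 192 ± 9.57 and 185 ± 12.8 CPM, which did not pass (log2 fold change -0.05, adjusted p = 0.563, edgeR with Benjamini-Hochberg). In the list of 19 integrin and heparan sulfate receptor genes, 4 rose, 1 fell and 14 did not pass, with the same counts adjusted over the list alone, and 2 fell without CYR61 replicate 1. Besides Itgam and Itgb2, the rises were those of Itgal (152 ± 4.88 to 177 ± 5.75 CPM) and the syndecan gene Sdc3 (567 ± 67.5 to 756 ± 17.7 CPM). The list passed as higher by camera (Benjamini-Hochberg adjusted p = 0.00955), and not by the same test with an estimated correlation (adjusted p = 0.0576 with an estimated correlation, the highest of 18 alternatives; the lowest, 0.000331, is from fry, which tests a list against no change and not against other genes). The transcript of CYR61 itself, Ccn1, had at most 1 count in any library, below the floor of 3 counts that a count of 0 allows (0.143 to 0.201 CPM by library), so no difference was detectable at this depth. Such floors cover counting error only.

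In the list of inflammatory cytokines, chemokines and NF-kB feedback genes, 7 of 23 tested members rose, 1 fell and 15 did not pass, against 9 and 1 adjusted over the list alone. Besides Saa3 and Ccl5, the itaconate-producing enzyme gene Acod1 rose 3.13-fold (8.57 ± 1.05 to 26.7 ± 7.90 CPM) and the cytokine signalling inhibitor gene Socs3 rose 2.84-fold (5.30 ± 0.573 to 15.0 ± 3.03 CPM). The list passed by camera (Benjamini-Hochberg adjusted p = 4.02e-07) and with an estimated correlation (adjusted p = 0.0484). Members outside the naming rule were looked at after their values were seen. Of these, Cxcl3 (0.0294 to 1.11 CPM), the adhesion receptor gene Icam1 (72.6 to 88.6 CPM) and the NF-kB subunit gene Relb (27.7 to 32.1 CPM) rose. The 1 member that fell was Ccl3, from 32.8 to 28.7 CPM, a call lost without control replicate 2 or 6, without CYR61 replicate 1 or 2 and in the 8 libraries of the replicate block with or without the block. Tnf stood at 10.9 and 11.1 CPM, Nfkb1 at 137 and 137 CPM, and the NF-kB feedback genes Nfkbia and Tnfaip3 at 69.9 and 72.0 CPM and at 30.0 and 30.5 CPM, none of these 4 passing. Il1b, Il6, Il12b and Nos2 were too low to be tested, with at most 16, 1, 0 and 7 counts in a library.

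Interferon-stimulated genes moved together. Of 29 tested members, 26 rose, 0 fell and 3 did not pass, with 28 rises adjusted over the list alone. Without CYR61 replicates 1 and 4 together, a fit chosen after seeing the data, 15 rose and 0 fell. The guanylate-binding protein genes Gbp2 and Gbp3 rose 2.04-fold (10.3 ± 1.51 to 21.1 ± 2.17 CPM) and 1.69-fold (8.81 ± 1.01 to 14.9 ± 0.946 CPM), the nucleic acid sensor gene Zbp1 rose 1.96-fold (21.3 ± 3.02 to 41.7 ± 3.67 CPM) and Ifit2 rose 1.48-fold (50.8 ± 4.96 to 74.9 ± 7.57 CPM). The median member stood at 1.32 times control. The list passed by camera (Benjamini-Hochberg adjusted p = 3.41e-24) and with an estimated correlation (adjusted p = 0.0429). Of 11 genes of MHC class II presentation, 5 rose and 0 fell (6 and 0 adjusted over the list alone). They included H2-Ab1 (7.90 ± 0.597 to 10.6 ± 1.56 CPM), H2-Eb1 (4.36 ± 0.98 to 6.43 ± 1.36 CPM), Ifi30 (139 ± 5.87 to 160 ± 7.03 CPM) and Ctss, which rose 1.07-fold. Only 2 rose with scaling by library size alone, and also when control replicate 3 or 5 or CYR61 replicate 2 or 3 was left out. The call of H2-Eb1 was lost in 10 and that of Ctss in 11 of 25 alternatives. That list passed by camera as well (Benjamini-Hochberg adjusted p = 9.47e-05, and adjusted p = 0.0429 with an estimated correlation).

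Genes of cholesterol biosynthesis and uptake rose almost as a whole: 21 of 24 tested members rose, 0 fell and 3 did not pass, with 23 rises adjusted over the list alone. The farnesyl diphosphate synthase gene Fdps rose 1.41-fold (56.3 ± 2.73 to 79.6 ± 2.61 CPM) and Sqle, which encodes squalene epoxidase, rose 1.32-fold (52.1 ± 1.76 to 68.9 ± 4.14 CPM). The list had the lowest p of all (camera, Benjamini-Hochberg adjusted p = 5.59e-29) and passed with an estimated correlation (adjusted p = 0.00102). In the list of LXR and PPAR lipid handling genes, 7 of 26 rose and 1 fell, against 8 and 2 adjusted over the list alone. Its 4 members of lowest p were fatty acid synthesis and binding genes: Scd2 (158 ± 4.64 to 221 ± 5.96 CPM), Scd1 (28.7 ± 2.16 to 37.99 ± 2.06 CPM), Fabp5 (547 ± 21.4 to 685 ± 22.7 CPM) and Fasn (206 ± 8.64 to 244 ± 19.1 CPM). The member that fell was Pparg (17.2 ± 1.08 to 13.9 ± 1.05 CPM). With scaling by library size alone 6 members rose and 4 fell, and the median log2 fold change went from 0.05 to 0.005. This list passed by camera (Benjamini-Hochberg adjusted p = 0.0075), and not with the correlation estimated (adjusted p = 0.133 with an estimated correlation, range over 18 alternatives 0.000635 to 0.133, the low end being from fry).

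Glycolysis and hypoxia genes rose in 14 of 26 tested members and fell in 1, against 16 and 1 adjusted over the list alone. With scaling by library size alone, 8 rose and 1 fell, and without CYR61 replicates 1 and 4 together, 9 and 1. The members of lowest p encode glycolytic enzymes: Pgk1 (149 ± 8.07 to 195 ± 9.89 CPM), Eno1 (376 ± 16.8 to 455 ± 8.19 CPM), Ldha (282 ± 8.37 to 336 ± 12.6 CPM) and Pfkl (48.9 ± 1.83 to 57.8 ± 1.95 CPM). The member that fell was Vegfa (86.1 ± 4.59 to 75.7 ± 6.75 CPM), whose groups overlap and whose call was lost without control replicate 2 or 3 or without CYR61 replicate 2, 3 or 4. The list passed by camera (Benjamini-Hochberg adjusted p = 3.78e-08) and with an estimated correlation (adjusted p = 0.0168). Of the unfolded protein and amino acid stress genes, 5 of 20 rose and 0 fell, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000433, and adjusted p = 0.0429 with an estimated correlation). The members of lowest p were endoplasmic reticulum chaperone genes: Calr rose 1.32-fold (466 ± 35.1 to 616 ± 15.2 CPM), Hspa5 1.203-fold, Pdia4 1.18-fold and Hsp90b1 1.13-fold. Of the oxidative stress and NRF2 genes, 5 of 21 rose and 0 fell (5 and 1 adjusted over the list alone), among them Slc7a11 (9.52 ± 2.20 to 16.6 ± 2.91 CPM), Sod2 (63.7 ± 5.07 to 91.4 ± 10.6 CPM), Hmox1 (195 ± 8.32 to 236 ± 2.88 CPM) and Tkt (1.098-fold). Their list passed by camera (Benjamini-Hochberg adjusted p = 0.00732), and not with the correlation estimated (adjusted p = 0.233 with an estimated correlation, range over 18 alternatives 0.000371 to 0.233). It did not pass with the replicate block either (camera, Benjamini-Hochberg adjusted p = 0.219). Its median log2 fold change of 0.045 became 0 with scaling by library size alone.

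Of 26 phagocytosis and efferocytosis receptor genes tested, 10 rose, 3 fell and 13 did not pass, against 12 and 3 adjusted over the list alone. Only 1 fell without CYR61 replicate 1. Beside Marco, the immunoglobulin receptor gene Fcgr1 rose 1.63-fold (100.6 ± 9.13 to 164 ± 7.41 CPM) and the scavenger receptor gene Msr1 rose 1.47-fold (76.3 ± 7.44 to 112 ± 10.4 CPM), and Cd300a, above, fell. The list passed by camera (Benjamini-Hochberg adjusted p = 6.41e-05), and not with the correlation estimated (adjusted p = 0.212 with an estimated correlation, range over 18 alternatives 1.93e-07 to 0.212). In the list of matrix metalloproteinases, inhibitors and matrix genes, 9 of 21 rose and 0 fell, against 11 and 1 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 8.19e-05, and adjusted p = 0.0429 with an estimated correlation). Beside Mmp14, these included Tgfbi (467 ± 14.7 to 575 ± 26.8 CPM), Adam9 (180 ± 6.17 to 212 ± 10.5 CPM) and the fibronectin gene Fn1 (11.5 ± 1.47 to 15.9 ± 1.895 CPM). With scaling by library size alone, 6 rose and 1 fell. Mmp9 lay below the expression minimum of the naming rule and was looked at after its value was seen, at 0.0931 ± 0.0725 and 2.38 ± 1.22 CPM. Of 30 lysosome genes, 4 rose and 1 fell (9 and 2 adjusted over the list alone), against 7 rises without control replicate 7, and 3 falls without CYR61 replicate 1 or with scaling by library size alone. The cathepsin genes Ctsl (504 ± 36.3 to 668 ± 26.3 CPM), Ctsz and Ctsh rose, and Atp6v0d2 fell (64.2 ± 3.59 to 53.9 ± 1.68 CPM). The lysosome list passed by camera (Benjamini-Hochberg adjusted p = 0.0125), but not with an estimated correlation (adjusted p = 0.505 with an estimated correlation, range over 18 alternatives 0.00176 to 0.505). With scaling by library size alone its median log2 fold change went from 0.043 to -0.002 and it did not pass (camera, Benjamini-Hochberg adjusted p = 0.228).

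Of 32 cell cycle genes tested, 12 fell, 1 rose and 19 did not pass, against 18 and 6 adjusted over the list alone, and 7 fell without CYR61 replicates 1 and 4 together. Mki67, a marker of proliferating cells, fell from 680 ± 21.7 to 535 ± 32.7 CPM, the kinetochore genes Cenpf and Cenpe fell from 105 ± 2.28 to 82.1 ± 4.08 CPM and from 83.0 ± 2.65 to 69.8 ± 3.26 CPM, and the mitotic regulator gene Cdc20 fell from 42.5 ± 1.802 to 35.1 ± 3.08 CPM. The 12 that fell all act in G2 or mitosis, and the 1 that rose, E2f1 (32.4 to 36.1 CPM, named after its value was seen), is a regulator of entry into S phase and lost its call in 14 of 25 alternatives. The list passed as lower by camera (Benjamini-Hochberg adjusted p = 0.000174), but not with an estimated correlation (adjusted p = 0.22 with an estimated correlation, range over 18 alternatives 2.27e-05 to 0.22). The 13 mitochondrially encoded genes also passed as lower by camera (Benjamini-Hochberg adjusted p = 0.024), although only mt-Nd6 fell as a single gene (189 ± 18.6 to 152 ± 19.4 CPM), also when adjusted over the list alone. The next members by p, mt-Nd2 (248 ± 28.2 and 215 ± 43.2 CPM), mt-Atp8 (77.1 ± 13.8 and 67.0 ± 11.9 CPM) and mt-Co2 (870 ± 94.8 and 801 ± 117 CPM), did not pass. The list's call was lost with an estimated correlation (adjusted p = 0.57 with an estimated correlation, range over 18 alternatives 0.0016 to 0.988). Without CYR61 replicate 1, in which 0.954% of counts were mitochondrial against 1.32 to 1.39% in the other CYR61 libraries, the list turned to higher (camera, Benjamini-Hochberg adjusted p = 0.837).

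The other 4 lists did not pass by camera. Alternative activation genes (Benjamini-Hochberg adjusted p = 0.718) split into 3 that rose and 4 that fell of 13 tested (4 and 4 adjusted over the list alone), with rises of the interleukin 4 receptor gene Il4ra (134 ± 7.88 to 179 ± 16.6 CPM) and Fn1 and falls of Cd163 (18.6 ± 1.32 to 14.7 ± 1.53 CPM) and Pparg. Of 11 osteoclast genes (camera, Benjamini-Hochberg adjusted p = 0.693), 3 rose and 2 fell (3 and 3 adjusted over the list alone), among them Src and Acp5, which rose, and Itgb3 and Atp6v0d2, which fell. Of 22 immediate early genes (camera, Benjamini-Hochberg adjusted p = 0.184), Ier3 rose, and 3 fell (1 and 4 adjusted over the list alone), Nr4a1 and Egr2 among them, the calls of Egr2 and Nr4a1 being lost in 8 and 3 of 25 alternatives. The number that fell was 1 without control replicate 6 or CYR61 replicate 4, and 0 in the 8 libraries of the replicate block (with or without it) and without CYR61 replicates 1 and 4 together. Myc stood at 2.21 ± 0.299 and 1.57 ± 0.27 CPM and did not pass. Of 15 growth factor and angiogenic factor genes (camera, Benjamini-Hochberg adjusted p = 0.747), 0 rose and only Vegfa fell, a call given above as lost without any 1 of 5 libraries; the counts were the same adjusted over the list alone. Csf1 (1.34 ± 0.0832 and 1.803 ± 0.404 CPM), Pdgfc (7.52 ± 0.48 and 8.87 ± 1.44 CPM) and Gdf15 (19.1 ± 3.16 and 16.4 ± 1.10 CPM) did not pass.

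**Figure D3:**
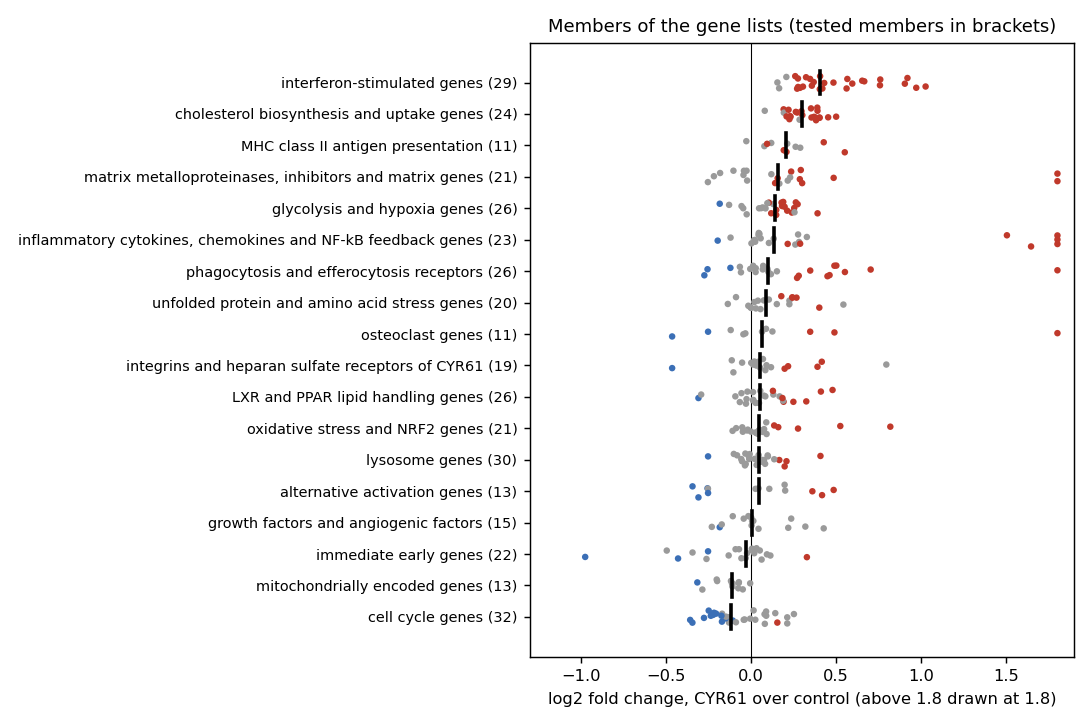
Log2 fold change of CYR61 over control (horizontal axis) for each tested member of the 18 gene lists (1 row per list, number of tested members in brackets); red points rose, blue points fell and grey points did not pass by edgeR, and the black bar is the list's median. The medians run from 0.405 for interferon-stimulated genes to -0.119 for cell cycle genes, and points above 1.8 are drawn at 1.8.

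Markers of cell types that a marrow culture can hold were tested as a separate set of lists. Of 11 macrophage markers, 6 rose and 0 fell (8 and 0 adjusted over the list alone). The rises included Fcgr1, Aif1 (16.9 ± 1.81 to 25.2 ± 2.35 CPM) and Adgre1, which encodes F4/80 (744 ± 31.9 to 918 ± 72.4 CPM). The list passed by camera (Benjamini-Hochberg adjusted p = 1.71e-06, and adjusted p = 0.0152 with an estimated correlation). With scaling by library size alone, 4 rose and 0 fell, and its median log2 fold change went from 0.151 to 0.106. Of 6 inflammatory monocyte markers, 3 rose and 1 fell, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0419, and adjusted p = 0.233 with an estimated correlation). Ly6c2 rose from 0.0917 ± 0.0389 to 0.935 ± 0.325 CPM and Vcan from 4.96 ± 0.91 to 8.77 ± 1.39 CPM, and Cx3cr1 fell from 48.0 ± 4.03 to 34.7 ± 3.99 CPM. The endothelial list passed as lower (camera, Benjamini-Hochberg adjusted p = 0.0419, and adjusted p = 0.233 with an estimated correlation) on 3 tested members, of which Vwf, the gene of von Willebrand factor, fell from 146 ± 5.09 to 121 ± 8.14 CPM, and Kdr (4.88 ± 0.684 and 4.16 ± 0.525 CPM) and Egfl7 (5.24 ± 0.534 and 4.91 ± 1.01 CPM) did not pass. The neutrophil, dendritic cell, B cell, megakaryocyte and fibroblast lists, with 2 or 3 tested members each, did not pass (camera, Benjamini-Hochberg adjusted p = 0.399, 0.874, 0.399, 0.878 and 0.878), and the megakaryocyte list had a median log2 fold change of -0.105 while its test pointed to higher. Single members of these lists that changed were S100a8 (0.97 to 1.69 CPM), Pf4 (4.20 to 7.54 CPM) and Ighm (61.3 to 47.3 CPM), named after their values were seen. The erythroid list had 1 tested member, Alas2, and the T and NK cell list and the mast cell and basophil list had 0.

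Libraries differed in how expression related to base composition and transcript length. Across 9861 protein-coding genes, which are not independent replicates, the rank correlation of a library's deviation from the mean with GC content was 0.522 in CYR61 replicate 1 and -0.127 to -0.022 in the other CYR61 libraries, against -0.331 to 0.304 in controls. That with transcript length was -0.187 to -0.112 in the CYR61 libraries and -0.191 to 0.329 in controls. The log2 fold change between the groups had rank correlations of 0.173 with GC content and -0.224 with length. With both trends removed per library, a correction chosen after seeing the data, edgeR called 1402 genes, which included 1079 of the 1204.

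The authors' deposited table of this comparison lists 13999 genes, of which 1720 have an adjusted p under 0.05 there, 1099 higher and 621 lower. Of the 1186 genes called by edgeR that the authors' deposited table also lists, 1137 (95.9%) passed in both and 0 had opposite directions. Counted from the authors' side, 1137 of their 1720 genes passed by edgeR. Both comparisons use these libraries, so the overlap is not independent evidence. The deposited p-values imply 25.8 degrees of freedom, against 16.8 for a limma-voom fit with quality weights on the 11 libraries. The reason was not tested. The authors' fit may have drawn on further libraries, and it also lists 13999 genes where 15135 were tested here. Across the 13987 genes in both, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.911. For Itgam the authors' deposited table gives a log2 fold change of 0.407 (interval 0.348 to 0.47), for Mki67 -0.322 (-0.384 to -0.26) and for Itgav -0.072 (-0.187 to 0.0427).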

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

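In groups of 4 to 7 libraries, a library was singled out when its gap to the nearest other, divided by the group's range, exceeded Dixon's 95% critical value. Chance alone does this in about 1 of 20 groups: of 212 group values tested (named genes and library measures), 12 met it and 11 are expected, so the number as a whole does not exceed chance. All the tests of this part were fixed before the data were examined, except those of the GC and length trends.

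CYR61 replicate 1 accounts for 8 of the 12. Its gap was 0.886 of the group's range for Vegfa (85.8 CPM against 71.5 to 73.1 in the other 3 CYR61 libraries), 0.871 for Aspm (77.1 against 85.9 to 87.2 CPM), 0.979 for mt-Nd2 (151 against 236 to 238 CPM) and 0.833 for Slc7a11 (12.3 against 17.7 to 18.7 CPM). It was 0.925 for Msr1 (96.4 against 117 to 118 CPM), 0.831 for Pdia4 (75.3 against 78.0 to 78.6 CPM) and 0.847 for Hsp90b1 (380.0 against 409 to 414 CPM). It was 0.838 for the rank correlation of expression with GC content (0.522 against -0.127 to -0.022).

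CYR61 replicate 4 stood apart in its share of ribosomal RNA counts, by 0.854 of the range (2.41% against 0.246 to 0.562%). Among controls, replicate 2 stood apart for Pdgfc by 0.57 (8.50 against 6.96 to 7.62 CPM), replicate 7 for Gbp3 by 0.701 (10.99 against 8.04 to 8.92 CPM) and replicate 6 for Ifit2 by 0.571 (41.0 against 49.1 to 55.2 CPM).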

How the results depend on the processing

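Chosen after seeing the data were the GC and length correction, library quality weights, the fit without CYR61 replicates 1 and 4, and the 8 libraries without the block. Against 1204 called genes (806 higher, 398 lower), the alternatives that kept the total within 1.5 times gave 891 to 1484 genes. Scaling by library size alone gave 529 higher and 938 lower; its median log2 fold change of -0.052 against -0.008 goes with this. Leaving out 1 library gave 788 to 1372 genes, 583 to 903 higher and 205 to 469 lower, with the lowest values without CYR61 replicate 2 and the highest without control replicate 7; the cause was not tested. Stricter calls lower the count by construction: at least 1.5-fold left 152 (121 higher, 31 lower), and adjusted p under 0.01 left 640 (477 and 163). Without CYR61 replicates 1 and 4 together, 910 were called, 729 of them shared with the 1204. No pairing of the libraries by replicate number was seen. The 4 correlations of same-numbered libraries were -0.024, 0.009, -0.128 and 0.08, and CYR61 replicates 1 to 4 correlated best with controls 3, 5, 6 and 1. A pairing that left little trace in expression cannot be excluded this way. The replicate block over 8 libraries called 1261 genes (811 higher, 450 lower), and those libraries without it 1267.

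Of the gene lists, 14 passed (12 higher, 2 lower). An estimated correlation left 7 (7 higher, 0 lower). The integrin list lost its call at an estimated correlation of 0.0129, near the preset 0.01, and the interferon list kept its call at 0.501. A lost call therefore does not by itself show that the members of a list vary together. With 1 library left out, 13 to 14 passed, 12 to 12 higher and 1 to 2 lower. The number lower was 1 with no TMM, the replicate block, 1 surrogate variable, fry, without control replicate 1 or 4, without CYR61 replicate 1 and without CYR61 replicates 1 and 4 together, because the mitochondrial list no longer passed. Directions reversed, the cause not being tested, for alternative activation genes with the GC and length correction (adjusted p 0.988), growth factors with 1 surrogate variable (0.99) and without CYR61 replicate 1 (0.769; leaving out other libraries gave 0.428 without CYR61 replicate 4 to 0.937 without control replicate 1), and mitochondrial genes without CYR61 replicate 1 (0.837; the lowest was 0.00388 without CYR61 replicate 3). Egfl7 reversed without CYR61 replicate 4 (log2 fold change 0.03; the lowest was -0.178 without CYR61 replicate 1). Of the other values of named genes under an alternative, 2344 kept direction and side of the threshold, 93 lost and 6 gained a call. Of the calls by edgeR that the authors' deposited table lists, 95.87% passed there, against 96.36% of DESeq2's and 96.07% at a mean of at least 1 CPM. A model with sex as covariate was not run: all 11 libraries were of 1 sex. At this depth, 40.3% of simulated 1.2-fold changes were recovered.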

Other observations

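The GC and length correction reported in this part was chosen after seeing the data, and the gene families and phases were singled out after the lists had been tested. Families of protein-coding genes that share a symbol stem (281 with at least 6 tested members) were compared with all other genes by camera. With a preset correlation 15 families were higher and 2 lower, and with an estimated correlation 0 passed (all adjusted p at least 0.57). Of 15 Ifi genes, 12 rose and Ifi27 fell, with Ifi209 going from 47.2 ± 4.58 to 71.4 ± 2.72 CPM. All 6 Gbp genes and 5 of 7 Slfn genes rose. Of 10 Psmb genes, which encode proteasome subunits, 5 rose, among them the 3 catalytic subunits of the immunoproteasome: Psmb8 (89.4 ± 5.6 to 107 ± 0.722 CPM), Psmb9 (33.4 ± 3.02 to 39.4 ± 0.927 CPM) and Psmb10 (50.7 ± 3.75 to 61.2 ± 6.11 CPM). Of 14 Clec genes 7 rose and 0 fell, led by the C-type lectin receptor genes Clec4e (15.2 ± 1.94 to 34.5 ± 8.08 CPM) and Clec4n (2.78 ± 0.331 to 6.08 ± 1.24 CPM). The families that were lower were Smc (3 of 6 fell), whose products form chromosome-organising complexes, and the kinesin family Kif (8 of 29 fell, 1 rose). With scaling by library size alone, 11 Ifi, 5 Gbp, 4 Slfn, 3 Psmb and 5 Clec genes rose, and 4 Smc and 9 Kif genes fell. Among the higher families, Rpl and Mrpl had 0 of 49 members called. That scaling moved their median log2 fold changes from 0.049 to 0.004 and 0.005, and left 0 of 7 Psmc genes called, against 2.

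The number of called genes was set against other groupings of the same libraries. Of 100 splits of the 11 libraries into 4 and 7, only 1, the real split, gave as many as 1204 called genes, and the highest of the others gave 2. An arbitrary division of the libraries therefore did not give a count of this size. Every other split puts CYR61 and control libraries into the same part, which widens the spread there and favours low counts. The comparison cannot tell CYR61 from another difference that coincides with the groups.

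Of the tested members, 26 of 29 interferon-stimulated, 21 of 24 cholesterol and 7 of 23 inflammatory genes rose in CYR61 libraries, 54 in all. A GC or length trend between libraries is argued against as the whole cause, since 54 of the 54 still passed as higher after both trends were removed. CYR61 replicate 1, with the strongest GC trend, is not the origin either, since 50 of the 54 passed without it. Granulocytes mixed into the cultures would bring S100a8 and S100a9, their most abundant transcripts, but these rose together by 0.705 CPM while Saa3 rose by 43.4 CPM. A response of the macrophages to CYR61 stays a hypothesis; it was not tested against more monocyte-like cells (of 6 inflammatory monocyte markers 3 rose and Cx3cr1 fell from 48.0 to 34.7 CPM, the list did not pass with an estimated correlation, at camera Benjamini-Hochberg adjusted p = 0.233, and 6 of 11 macrophage markers rose), against traces of microbial material in the protein preparation, or against other differences between treated and control cultures, which this design cannot separate from CYR61.

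The cell cycle list fell in part. Of its 12 members that fell, 11 still passed after the GC and length correction, which argues against those trends as the whole cause. The 18 G2 and M phase members had a median log2 fold change of -0.174 with 0 above 0, and the 14 G1 and S phase members had a median of 0.084 with 11 above 0 (two-sided permutation test over genes, 100000 resamples, p = 5e-05; genes are not independent replicates). The phases were singled out after the list had been tested, so this p-value restates the pattern that prompted the split and adds no support. A lower share of cycling cells would lower both groups of genes. The G1 and S phase median above 0 argues against it as the only cause, although only 1 of these members passed as higher. The medians kept these signs in each of the 25 alternatives, with scaling by library size alone at -0.218 and 0.039. A candidate explanation is a shift of cycling cells away from G2 and M, or lower transcription of mitotic genes; these were not tested apart.

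Genes annotated as TEC (loci that await experimental testing), sense intronic, antisense or lincRNA, 1966 in all, included 27 that fell and 6 that rose. Their median log2 fold change was -0.118 against 0.001 for protein-coding genes, a gap of -0.119. The gap was -0.151 without CYR61 replicate 1, which argues against that library as the whole cause. After the GC and length correction it was -0.134. The trends were fitted on the 9861 more strongly expressed protein-coding genes and carried over to these classes. The result argues against the trends of those genes as the whole cause, and cannot decide on trends particular to the classes. Protein-coding genes matched on expression had a median of -0.024, and 100% of 1000 matched draws lay above the classes, so low expression alone is argued against. The share of these classes in the counts of the classes and protein-coding genes together, leaving out Malat1 and Neat1, was 0.901 ± 0.0621% in controls (n = 7) and 0.828 ± 0.026% with CYR61 (n = 4), which did not pass (two-sided exact permutation p = 0.0576; control replicate 7, at 0.802%, lay below 3 of the 4 CYR61 libraries). Among controls the share was highest in replicate 1 (0.9985%) and lowest in replicates 6 (0.859%) and 7, against 0.796 to 0.854% in the CYR61 libraries. The difference thus overlaps one among the controls. A candidate explanation is a lower proportion of unspliced or nuclear RNA in the CYR61 libraries, from the cells or from extraction, which was not tested. A trend along the numbering of the libraries was not tested either. As strand is not stated, antisense reads may belong to their partner genes.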
